A study of Mus musculus with 24 samples.

How the data were processed

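RNA of single mandibular prominences was measured on 24 Illumina mouse whole-genome bead arrays, 1 array per embryo, in 8 groups of 3 formed by 4 stages (E10, E11, E12 and E13) and 2 p63 genotypes (p63-/- and p63+/-). Groups and replicate numbers were taken from the sample labels. Per the labels, the samples of a genotype at a stage came from different litters and were not pooled, and p63-/- embryos had p63+/- littermates. The series title speaks of wild type, but the labels of these 24 samples give p63+/- and p63-/-, so the heterozygotes were used as the comparison group.

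The deposited probe table holds, per the file headers, an intensity and a detection p-value for each of 45281 probes and 24 arrays. The intensities are on a linear scale with a lowest value of 64.3, are all positive and are not scaled between arrays. The detection p-value ranks each probe among negative control beads in steps of 1 in 936. The series' own value table, the authors' processed values, is on a log2 scale, with array medians between 7.92 and 7.93 and a range from 7.62 to 16.0. Its values ranked the probes as the intensities of the same array did (rank correlation 1), which leaves the order of the authors' steps unknown. BeadStudio, lumi and RMA are named in the submitters' processing notes, without versions, roles or settings.

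Intensities were background-corrected, quantile-normalized and log2-transformed with limma's neqc in limma 3.58.1 under R 4.3.3, with an offset of 16. Each slide held the 6 arrays of 1 stage. The genotype differences were therefore taken within slides, whereas stage and slide cannot be told apart. At E11, E12 and E13 the p63-/- arrays occupied the first positions of the slide and the p63+/- arrays the last, and at E10 the genotypes were interleaved. The platform annotation gave 34885 probes 1 gene, 18 probes several and 10378 none. Of the named probes, 34807 matched a RefSeq gene of assembly GRCm38.p6 by gene identifier, and 0 symbols needed an update. No genome was used, and that table served for names and for the order of neighbouring genes.

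Probes with a detection p under 0.05 on at least 3 arrays were kept (24233). Each gene was represented by its probe with the highest mean over the 24 arrays, which left 12698 genes; where a gene's other probes disagree with it, the text says so. A gene not detected on any array of a group was given as a bound, "at least N-fold": the mean of the brighter group against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal. The same bound is given where a gene was detected on a minority of the arrays of a group. Arrays detected between 43.4% and 48.98% of the probes.

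Each gene was fitted in limma with a mean for each of the 8 groups, so that all arrays shared 1 estimate of the spread (16 residual degrees of freedom, 2.96 prior). The contrasts were p63-/- minus p63+/- at each stage, their average over 4 stages, the interaction of genotype with stage (an F test with 3 degrees of freedom), and E13 minus E10 within each genotype. Moderated p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Fold changes are on the normalized log2 scale, where background compresses the change of dim genes.

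Gene lists were fixed before the data were examined: keratins and desmosomes, hemidesmosome and epithelial basement membrane, p63 pathway and epidermal regulators, general epithelium, odontogenic epithelium signals, odontogenic mesenchyme, mandibular patterning mesenchyme, chondrogenic, osteogenic, skeletal muscle, endothelial, erythroid, neuron, glia and Schwann lineage, macrophage, proliferation, p53 targets, readouts of Wnt, Shh, Fgf and Bmp signalling, Notch pathway, immediate early and heat shock, and hypoxia and glycolysis. These 21 lists held 393 entries, of which 308 were measured. They were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 21 lists for the average and over 84 tests of a list at a stage. Lists of 36 visceral yolk sac endoderm genes and 12 hepatocyte genes were written after E10 p63-/- replicate 3 had been seen to stand apart.

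The genes named were set by a rule, also fixed before the data were examined. It took Trp63 first, then on the average the 15 lowest and 15 highest values among genes past the threshold with the same sign at 4 stages, and at each stage the 8 lowest and 8 highest. For the interaction it took the 10 smallest p and for E13 minus E10 in p63+/- the 10 lowest and 10 highest. In each list it took up to 4 members with the largest change past the threshold, or 2 as values where none passed. Sex-linked genes and unnamed symbols were left out of the rankings, and the text gives a selection of the genes the rule took. Outside the rule, and named after their values were seen, are Pkp1, Cldn4, Krt19, Etv5, Anxa8 and Cldn23, for which all alternatives were also run, and Alx1, Hoxa2, Hoxb2, Hoxd3, Alb, Afp, Ttr and Apoa1.

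Samples sharing a replicate number were checked for pairing through the correlation of their deviations from the group means. At E12 the same-number correlations lay between 0.285 and 0.427, and at E13 between 0.255 and 0.628, each above 0.1, and all 6 arrays of either stage correlated best with their own number. The numbers were therefore read as pairing the samples at these stages, from the data and not from a label, and a fit with the replicate number as a block is given where it changes a call there. The main counts and p-values, also at E12 and E13, come from the fit without pairing.

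The model fit was tested on simulated normalized values with 200 changed genes among 12698. Of genes changed 2-fold it recovered 77.6% for the genotype difference at E10, 80.6% at E11, 79.1% at E12 and 76.1% at E13, and 100% on the average over stages, where it made 9 false calls. Of genes changed 1.5-fold it recovered 28.4%, 40.3%, 32.8% and 34.3% at these stages and 85.1% on the average. For the interaction it recovered 59.7% at 2-fold. The simulated noise was normal and independent between genes and arrays, without pairing or an array that stands apart. Background correction, normalization, the detection filter and probe choice were not part of the simulation, so recovery in these data may be lower. Alternatives tried were quantile normalization without background correction, an offset of 50, the authors' processed values, no detection filter, a filter at p under 0.01 on at least 6 arrays, the replicate block, array weights, the fit of the compared arrays alone, all detected probes, a fold change of at least 1.5, an estimated correlation for lists, and leaving out each array in turn. The fits without E10 p63-/- replicate 3 and with the Xist level as a covariate were chosen after seeing the data.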

Results

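The mandibular prominence is the swelling of the first pharyngeal arch that gives rise to the lower jaw and its teeth. Its RNA was measured on 24 single-colour Illumina bead arrays, each hybridised with the prominence of 1 mouse embryo. The embryos carried the targeted p63 allele on both chromosomes (p63-/-) or on 1 (p63+/-), and were collected on embryonic days 10, 11, 12 and 13. That gave 8 groups of 3 embryos, and at each stage the embryos of a genotype came from 3 different litters. p63 (gene symbol Trp63) is a transcription factor that stratified epithelia need to form, and mice without it lack teeth while a lower jaw forms. The comparison group was heterozygous throughout, so every genotype difference is p63-/- against p63+/- and not against wild type. Arrays detected between 43.4% and 48.98% of the 45281 probes, and 12698 genes entered the tests. With 3 arrays per group, the number of arrays limits the precision of each value.

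Trp63 (gene identifier 22061) has 2 probes, of which 1 lay near background (4.73 to 5.69), did not separate the genotypes and did not pass the detection filter. The brighter Trp63 probe was read on every array, as a check of the labels. Its normalized log2 intensity lay between 8.97 and 9.89 on the 12 p63-/- arrays and between 10.19 and 11.32 on the 12 p63+/- arrays, with no overlap. Averaged over the stages the difference was -1.32 (SE 0.12, adjusted p = 6.33e-07), with means of 9.39 ± 0.35 against 10.71 ± 0.34 (SD over stages and embryos, n = 12 arrays per genotype). At E10 Trp63 was 9.38 ± 0.37 against 11.06 ± 0.26 (SD, n = 3), a difference of -1.67 (SE 0.24, adjusted p = 0.000646). The differences were -1.28 (SE 0.24, adjusted p = 0.0131) at E11 and -1.24 (SE 0.24, adjusted p = 0.0212) at E13. At E12 Trp63 differed by -1.08 (SE 0.24, adjusted p = 0.0655) and did not pass the threshold; over the alternatives its adjusted p ran from 0.0453 to 0.144, and it passed with quantile normalization alone, with an offset of 50 and without E10 p63-/- replicate 3. The E11 call was lost without E11 p63-/- replicate 3, p63+/- replicate 1 or p63+/- replicate 3 (highest adjusted p = 0.0865), and the E13 call without E13 p63-/- replicates 2 or 3 or p63+/- replicates 2 or 3 (highest adjusted p = 0.186). With the compared arrays alone in the fit, the E10, E11 and E13 calls were lost (adjusted p = 0.0686, 0.136 and 0.127). Where the probe lies relative to the disrupted exons is not given in the sources used here, so it reports transcript from the locus and not whether p63 protein was made.

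Averaged over the 4 stages, Col17a1, the transmembrane collagen of hemidesmosomes, was at least 6.01-fold lower in p63-/- prominences (adjusted p = 5.7e-07). It was detected on 5 of 12 p63-/- arrays and 11 of 12 p63+/- arrays. Krt14, the type I keratin of basal cells in stratified epithelia, was 4.74-fold lower, at 9.45 ± 0.82 against 11.70 ± 1.27 (SD, n = 12 per genotype; log2 difference -2.24, SE 0.23, adjusted p = 2.82e-06). Krt8 and Krt18, the keratin pair of simple epithelia, were 3.56-fold and 3.47-fold higher, with log2 differences of 1.83 (SE 0.14, adjusted p = 3.46e-08) and 1.80 (SE 0.13, adjusted p = 3.46e-08). Cldn3, a tight junction claudin, was 3.13-fold higher, at 9.09 ± 0.31 against 7.44 ± 0.47. Of 12698 genes, 298 passed the threshold in limma, 127 lower and 171 higher in p63-/-, and 1290 had an unadjusted p under 0.05.

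Among the other genes with the lowest values on this average, Trim29 was at least 5.14-fold lower (adjusted p = 2.4e-10), detected on 5 of 12 p63-/- arrays and on all p63+/- arrays. Fermt1, the kindlin that activates integrins in keratinocytes, differed by -2.19 (SE 0.11, adjusted p = 1.95e-10). Sfn, a 14-3-3 protein of stratified epithelia, differed by -2.12 (SE 0.16, adjusted p = 6.5e-08), and Kremen2, a receptor for the Wnt inhibitor Dkk1, by -1.80 (SE 0.13, adjusted p = 2.13e-08). The keratins Krt17 and Krt15 differed by -1.83 (SE 0.22) and -1.43 (SE 0.21), with adjusted p of 2.21e-05 and 0.000273. Krt5, detected on 1 of the 12 p63-/- arrays and on 8 of the 12 p63+/- arrays, was at least 2.26-fold lower (adjusted p = 1.84e-05). Fxyd3 differed by -1.73 (SE 0.15, adjusted p = 3.1e-07) and Nt5e, the ecto-5'-nucleotidase CD73, by -1.55 (SE 0.19, adjusted p = 3.98e-05). Wnt3a, a Wnt ligand, Diras2 and Pltp, a phospholipid transfer protein, were detected on 2, 3 and 4 of 12 p63-/- arrays. They were at least 2.37-fold, 2.57-fold and 2.43-fold lower (adjusted p from 6.05e-09 to 1.31e-06). The brightest of 5 probes of Ctsa, the lysosomal cathepsin A, read -1.65 (SE 0.08, adjusted p = 2.4e-10), while its 4 other probes read between -0.02 and 0.23 and none of them passed.

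Among the genes higher in p63-/- on this average, Cbln1, a secreted synaptic organiser, rose by 1.54 (SE 0.11, adjusted p = 1.46e-08). Cldn10, a claudin, rose by 1.38 (SE 0.17, adjusted p = 5.18e-05) and Marveld3, a further tight junction protein, by 1.09 (SE 0.08, adjusted p = 6.5e-08). The growth factor Fgf17 rose by 1.32 (SE 0.14, adjusted p = 7.04e-06), the actin-bundling Espn by 1.35 (SE 0.14, adjusted p = 5.6e-06) and the kinase Nuak2 by 1.21 (SE 0.12, adjusted p = 3.76e-06). Krt7, a simple epithelial keratin, the membrane protease Prss8 and the plakophilin Pkp2 rose by 1.19 (SE 0.13), 1.23 (SE 0.17) and 1.10 (SE 0.15), with adjusted p of 1.04e-05, 0.000139 and 0.000147. C2cd4a read 1.43 (SE 0.22, adjusted p = 0.000467) on its brightest probe and 0.35 (SE 0.08) on its other probe. Espn's other probe, near background, read -0.08 (SE 0.11) and did not pass. Fgfbp1, a carrier of fibroblast growth factors detected on 5 of 12 p63+/- arrays, was at least 1.75-fold higher (adjusted p = 0.00103). Tmem125 rose by 1.06 (SE 0.18, adjusted p = 0.00124); with the authors' processed values Tmem125 did not pass (adjusted p = 0.0507, the highest over the alternatives).

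In the list of keratins and desmosomes, 5 of 12 measured genes fell and none rose on the average (6 fell when adjusted over the list alone; camera adjusted p = 3.52e-09, and adjusted p = 0.0284 with an estimated correlation). They were Krt5, Krt14, Krt15, Krt17 and Pkp1, a desmosomal plakophilin (adjusted p = 0.0488). The call of Pkp1 was lost in 19 of the 24 runs that each left out 1 array (highest adjusted p = 0.101) and under 5 of the other alternatives. In the hemidesmosome and epithelial basement membrane list 4 of 15 fell and none rose (5 fell when adjusted over the list alone; adjusted p = 1.08e-07, and adjusted p = 0.0185 with an estimated correlation). These were Col17a1, Fermt1, the integrin subunit Itgb4 (-1.25, SE 0.18, adjusted p = 0.000217) and the anchoring fibril collagen Col7a1 (-0.69, SE 0.16, adjusted p = 0.0243). The Col7a1 call was lost without any of 7 arrays, with a highest adjusted p of 0.0541, and with the authors' processed values (adjusted p = 0.0508): E11 p63-/- replicate 2, E11 p63+/- replicates 1 and 3, E12 p63+/- replicates 1 and 2, E13 p63-/- replicate 2 and E13 p63+/- replicate 2. Of 18 measured genes of the p63 pathway and epidermal regulators, 6 fell and 1 rose (8 and 1 when adjusted over the list alone; adjusted p = 1.22e-08, and adjusted p = 0.00895 with an estimated correlation). Those that fell included Sfn, Trim29, the epidermal differentiation factor Zfp750 (at least 1.7-fold lower, adjusted p = 6.49e-05, detected on 4 of 12 p63-/- arrays) and the Notch ligand Jag2 (-1.28, SE 0.08, adjusted p = 2.91e-09).

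The general epithelium list, which holds genes of simple and of all epithelia, moved the other way: 14 of 22 measured genes rose and none fell (19 rose when adjusted over the list alone). Its median difference was 0.55, and its camera adjusted p of 3.08e-43 became adjusted p = 0.0014 with an estimated correlation. Besides Krt8, Krt18, Krt7, Cldn3, Prss8 and Marveld3, the list's risers included the claudins Cldn4 (0.70, SE 0.08, adjusted p = 1.88e-05) and Cldn6 (0.97, SE 0.13, adjusted p = 6.48e-05) and the keratin Krt19 (0.59, SE 0.14, adjusted p = 0.0201). In the Notch pathway list 2 of 12 fell, Jag2 and the Notch target Nrarp (-0.31, SE 0.05, adjusted p = 0.00142), and none rose (4 fell when adjusted over the list alone; adjusted p = 0.000318, and adjusted p = 0.0284 with an estimated correlation).

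**Figure D1:**
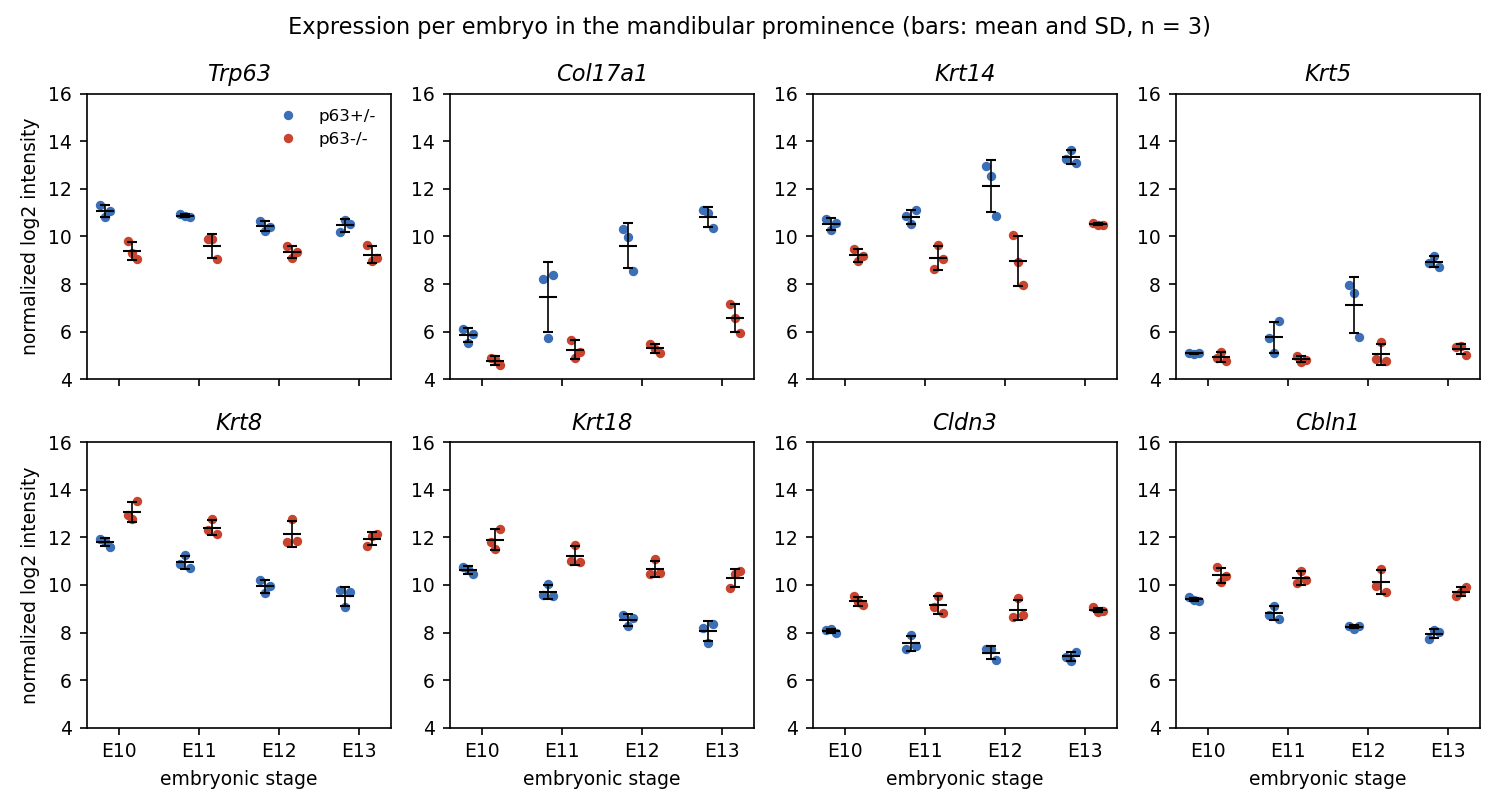
Normalized log2 intensity (vertical axis) by embryonic stage (horizontal axis) of Trp63 and 7 genes named for their size of change, with 1 dot per embryo and a black bar for the mean and SD of 3 embryos. The p63-/- dots of Col17a1, Krt14 and Krt5 lie below the p63+/- dots at E12 and E13, and those of Krt8, Krt18, Cldn3 and Cbln1 lie above them.

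Genes of tooth signalling passed as lists at the preset correlation but not with an estimated one. Among odontogenic epithelium signals 2 of 15 measured genes fell and none rose over all genes tested (4 fell and 2 rose when adjusted over the list alone). The 2 were Wnt4, a Wnt ligand (-0.59, SE 0.12, adjusted p = 0.00752), and Edaradd, the adaptor of the ectodysplasin receptor (-0.90, SE 0.13, adjusted p = 0.000252); a dimmer Edaradd probe read -0.24 (SE 0.08) and did not pass. The list's adjusted p was 0.0291, and adjusted p = 0.273 with an estimated correlation. Of 19 readouts of Wnt, Shh, Fgf and Bmp signalling 4 fell and 1 rose (5 and 1 when adjusted over the list alone; adjusted p = 0.0239, and adjusted p = 0.387 with an estimated correlation). The Wnt targets Sp5, Nkd1, Notum and Axin2 fell by 0.95, 0.45, 0.40 and 0.36 on the log2 scale, and the Fgf target Etv5 rose by 0.27 (SE 0.07, adjusted p = 0.0494). The calls of Axin2, Notum and Etv5 were lost in 17, 19 and 19 of the 24 runs that each left out 1 array, with highest adjusted p of 0.0969, 0.0927 and 0.104, and under 4, 4 and 3 of the other alternatives. Both lists' calls were also lost without E10 p63-/- replicate 3 (adjusted p = 0.0562 for each) and with the strict filter (0.0790 and 0.0661). The odontogenic epithelium list was lost as well with the authors' processed values (0.0536) and the Xist covariate (0.0804). The readouts list was also lost with array weights (adjusted p = 0.216). Finding 7 lists on the average was within what random regroupings of the arrays gave.

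In the main fit genes of the jaw mesenchyme and of its skeletal and muscle lineages did not pass as lists on the average. Of 14 odontogenic mesenchyme genes 0 passed in limma over all genes (2 at an unadjusted p under 0.05), and 1 rose and 1 fell when adjusted over the list alone (adjusted p = 0.870); its median was 0.03 and its mean -0.02. Tfap2b read 0.29 (SE 0.08, adjusted p = 0.0951) and Osr2 -0.66 (SE 0.20, adjusted p = 0.111); both passed with the replicate number as a block (adjusted p = 0.0129 and 0.0125), and Osr2 with array weights (0.0377). Lhx6 passed with the Xist covariate (adjusted p = 0.0308). Of 16 mandibular patterning genes 1 rose, Edn1, the endothelin that patterns the lower jaw (0.62, SE 0.12, adjusted p = 0.00347), and the list did not pass (adjusted p = 0.109). Whole prominences do not show whether Edn1 rose in mesenchyme or in epithelium. None of the 14 chondrogenic, 13 osteogenic or 18 skeletal muscle genes passed in limma, also when adjusted over the list alone, and 2, 0 and 0 of them had an unadjusted p under 0.05. The camera adjusted p were 0.275, 0.748 and 0.127. With the replicate block the mandibular patterning and skeletal muscle lists passed at the preset correlation (adjusted p = 0.0303 and 0.0197), and the patterning genes Alx1 and Foxf2 were lower with it (adjusted p = 0.0211 and 0.0354). Alx1 also passed with array weights (adjusted p = 0.0485). The chondrogenic gene Hapln1 passed with the block and with array weights (adjusted p = 0.00538 and 0.0441).

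Markers of other cells in the prominence also gave no list call on the average in the main fit. None of 14 endothelial, 10 erythroid, 16 neuronal, 7 glial and Schwann lineage, 13 macrophage, 17 proliferation or 12 hypoxia and glycolysis genes passed in limma, also when adjusted over the list alone. At an unadjusted p under 0.05 there were 1 neuronal, 2 hypoxia and glycolysis and 0 other such genes. Their camera adjusted p were 0.915, 0.275, 0.175, 0.506, 0.126, 0.974 and 0.0707. With array weights the erythroid and hypoxia lists passed (adjusted p = 0.00472 and 0.026), and with all detected probes the hypoxia list (0.0342). The neuronal gene Uchl1 passed with the replicate block and with array weights (adjusted p = 0.0223 and 0.0168). Of 16 p53 targets 1 fell, Phlda3 (-0.39, SE 0.06, adjusted p = 0.000493; list adjusted p = 0.0701), and of 15 immediate early and heat shock genes 1 rose, Atf3 (at least 1.37-fold, adjusted p = 0.00752, detected on 4 of 12 p63+/- arrays; list adjusted p = 0.483). The p53 target list passed with no detection filter (adjusted p = 0.0298) and without E10 p63-/- replicate 3 (0.0125). The median of the immediate early list was -0.03 while its mean was 0.04.

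**Figure D2:**
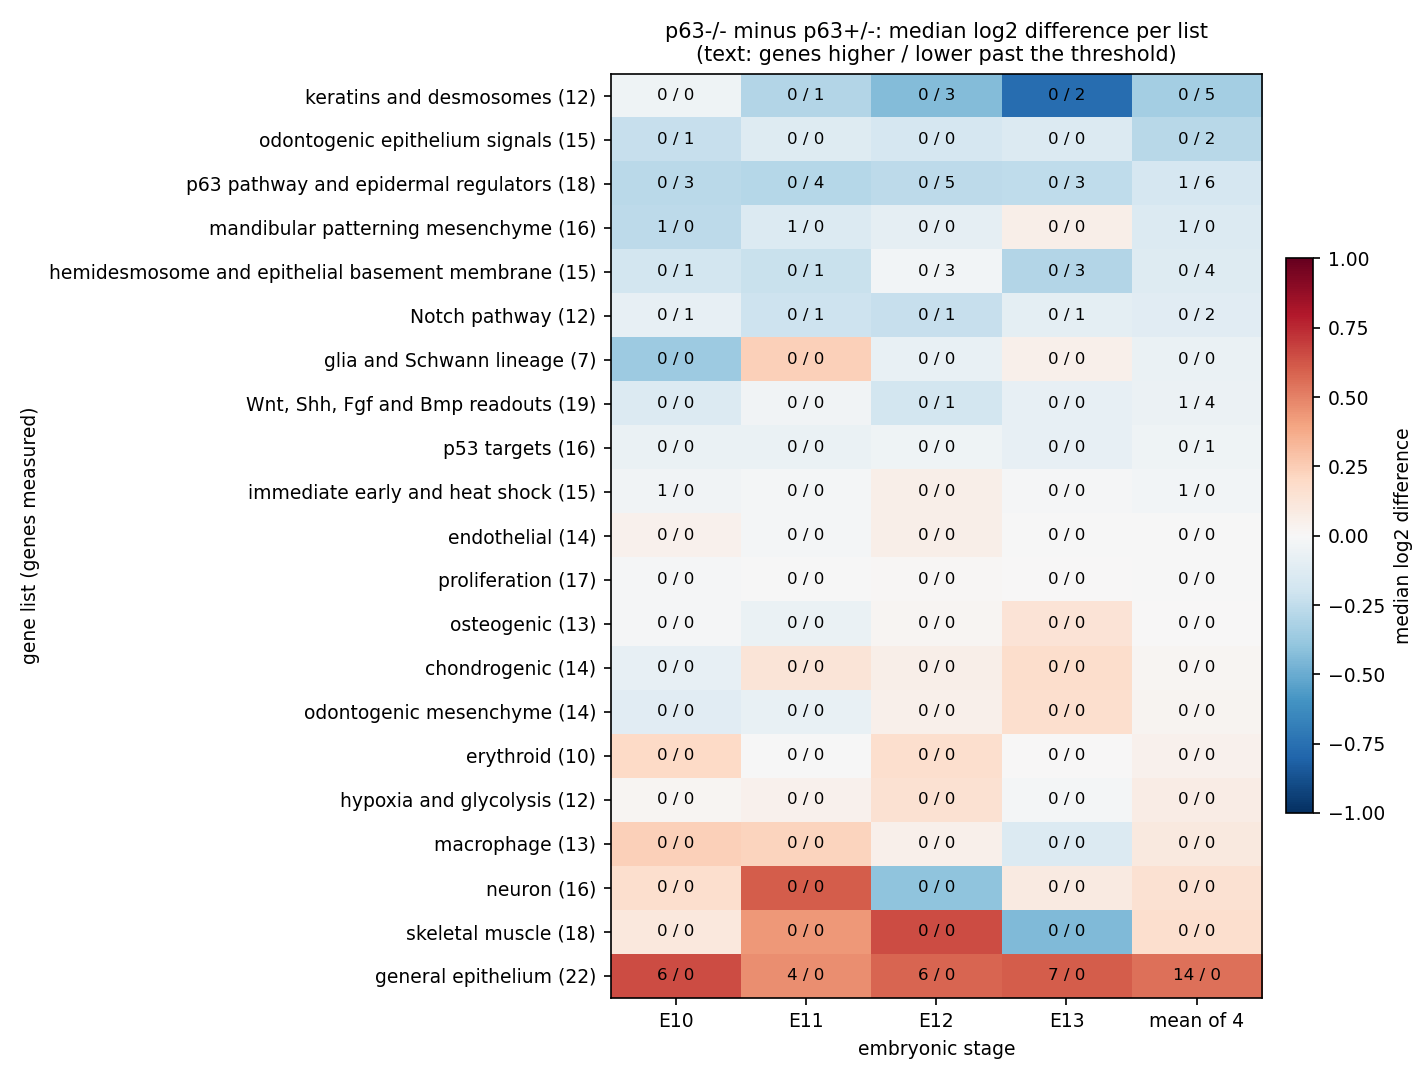
Median log2 difference, p63-/- minus p63+/- (colour, from -1 to 1), of each of the 21 gene lists (vertical axis, with the number of genes measured) at the 4 stages and on their mean (horizontal axis); the text in each cell counts the genes higher and lower past the threshold. The general epithelium list has 14 genes higher and 0 lower on the mean, and the keratin and desmosome list 0 higher and 5 lower.

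In limma 101 genes passed at E10, 62 lower and 39 higher in p63-/- prominences, with 1778 at an unadjusted p under 0.05. Kremen2 was at 6.20 ± 0.31 against 8.85 ± 0.27 (SD, n = 3 per genotype), a log2 difference of -2.65 (SE 0.26, adjusted p = 1.3e-05). Fermt1 differed by -1.98 (SE 0.21, adjusted p = 2.71e-05) and Jag2 by -1.66 (SE 0.16, adjusted p = 1.21e-05). Sfn, not above background on any E10 p63-/- array, was at least 4.12-fold lower (adjusted p = 0.000263). Trim29, Fxyd3 and Cpz, a carboxypeptidase, were each detected on 1 of 3 p63-/- arrays and were at least 3.66-fold, 3.24-fold and 3.01-fold lower, with adjusted p of 0.000194, 0.0007 and 0.00698. Quantile normalization without background correction gave 55 lower and 59 higher. The count was 430 without E10 p63-/- replicate 1, 60 without p63+/- replicate 1 and 51 without p63+/- replicate 3. The run with 430 kept p63-/- replicates 2 and 3, on which the yolk sac transcript Afp read 8.33 and 13.77, against at most 6.00 on the p63+/- arrays. Whether this raised the count was not tested. In a fit of the 6 E10 arrays alone, 26 genes passed and the calls of Trim29, Fxyd3, Cpz, Prr15l, Bmp3, Stx3 and Marveld3 were lost (adjusted p from 0.052 to 0.144), and with the authors' processed values that of Bmp3 was lost (adjusted p = 0.116).

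Higher at E10 were Prr15l (at least 3.1-fold, adjusted p = 0.000115, detected on 1 of 3 p63+/- arrays), the growth factor Bmp3 (1.68, SE 0.31, adjusted p = 0.00862), the glutathione transferase Gstt1 (1.45, SE 0.22, adjusted p = 0.00137) and the syntaxin Stx3 (1.34, SE 0.24, adjusted p = 0.00562). Mt3, a metallothionein, was at least 1.97-fold higher (adjusted p = 2.71e-05). In the general epithelium list 6 of 22 genes rose (12 when adjusted over the list alone; adjusted p = 0.0358 with an estimated correlation). Cldn3 rose by 1.25 (SE 0.21, adjusted p = 0.00341) and Marveld3 by 1.05 (SE 0.17, adjusted p = 0.00236). The differences of Krt8 and Krt18 were 1.26 (SE 0.27, adjusted p = 0.0285) and 1.27 (SE 0.26, adjusted p = 0.0236). Both calls were lost without E10 p63-/- replicate 3 or any of the 3 E10 p63+/- arrays, with highest adjusted p of 0.166 and 0.140, and in the fit of the E10 arrays alone (0.161 and 0.177). The Krt8 call was also lost with the replicate number as a block (adjusted p = 0.0574). In the p63 pathway list 3 of 18 genes fell, Sfn, Trim29 and Jag2 (5 fell and 2 rose when adjusted over the list alone; adjusted p = 0.00404, and adjusted p = 0.184 with an estimated correlation). The glia and Schwann lineage list was lower with 0 of its 7 genes passing in limma (2 at an unadjusted p under 0.05, and 2 lower when adjusted over the list alone; adjusted p = 0.0444, and adjusted p = 0.458 with an estimated correlation). Its member Sox10 passed as lower with the strict filter, the replicate block, array weights, the Xist covariate and the E10 arrays alone (adjusted p from 0.0139 to 0.0478). Ngfr passed as lower with the block (adjusted p = 0.0350).

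The array E10 p63-/- replicate 3 stood apart from the other E10 arrays and carried transcripts of visceral yolk sac endoderm, an extraembryonic tissue. On it Afp read 13.77 against a mean of 5.96 on the other 5 E10 arrays, Ttr 15.47 against 7.76 and Apoa1 15.12 against 7.78. Its mean correlation with the other E10 arrays was 0.959, against at least 0.982 for each of them, and 238 genes lay over 4-fold above the mean of the others. The general epithelium list was 0.69 higher in the median on this array than on the other 5. Without it 147 genes passed at E10, 94 lower and 53 higher, and 75 of the 101 were among them; 3 general epithelium genes then passed.

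**Figure D3:**
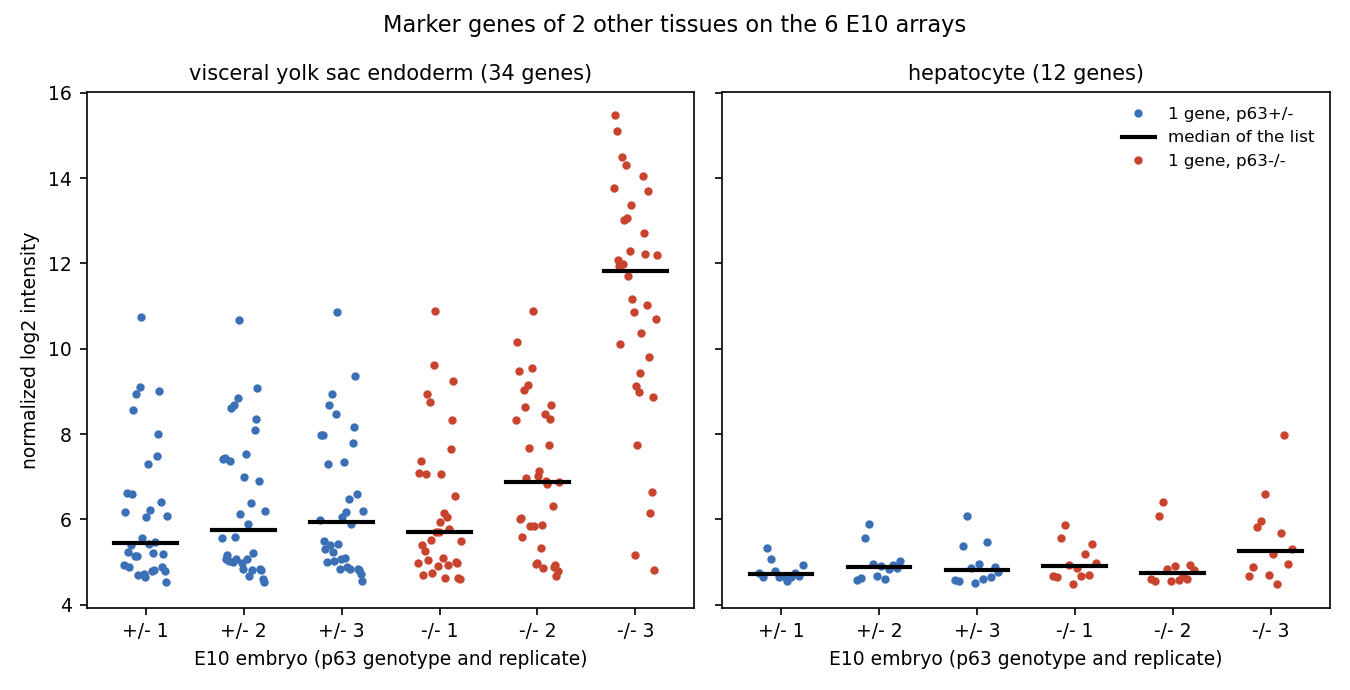
Normalized log2 intensity (vertical axis) of 34 visceral yolk sac endoderm genes (left) and 12 hepatocyte genes (right) on the 6 E10 arrays (horizontal axis), with 1 dot per gene and a bar for the median. On p63-/- replicate 3 the yolk sac genes lie a median of 5.45 above the mean of the other 5 arrays and the hepatocyte genes 0.26 above it.

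At E11, 65 genes passed in limma, 33 lower and 32 higher in p63-/- prominences, with 644 at an unadjusted p under 0.05. Kremen2 differed by -2.35 (SE 0.26, adjusted p = 6.53e-05) and Fermt1 by -2.31 (SE 0.21, adjusted p = 7.25e-06) (n = 3 per genotype). Sfn, Trim29 and Fxyd3 were each detected on 1 of 3 p63-/- arrays and were at least 4.31-fold, 3.67-fold and 4.04-fold lower, with adjusted p of 0.000361, 7.15e-05 and 0.000176. Cldn3 was at 9.14 ± 0.37 against 7.55 ± 0.30, a rise of 1.60 (SE 0.21, adjusted p = 0.000352), and Marveld3 rose by 1.02 (SE 0.17, adjusted p = 0.00523). Krt18 differed by 1.52 (SE 0.26, adjusted p = 0.00798) and Krt8 by 1.46 (SE 0.27, adjusted p = 0.0131). Both calls were lost without E11 p63-/- replicate 2 or p63+/- replicates 1 or 3 (highest adjusted p of 0.0724 and 0.105). That of Krt8 was also lost with the replicate number as a block (adjusted p = 0.0510). The count fell to 28 without E11 p63-/- replicate 2, 30 without p63+/- replicate 1 and 34 without p63+/- replicate 3. In a fit of the 6 E11 arrays alone, 26 genes passed and the calls of Fxyd3, Cldn3, Jag2, Krt8, Krt18 and Marveld3 were lost (adjusted p from 0.0505 to 0.166); with the authors' processed values 35 genes passed.

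Sst, the peptide hormone somatostatin, was at least 10.5-fold higher at E11 (adjusted p = 0.0133), at 9.06 ± 1.07 against 5.45 ± 0.25. Sst was detected on all 3 p63-/- arrays and on 1 of 3 p63+/- arrays. Its call was lost without p63-/- replicate 1 or p63+/- replicate 1 (highest adjusted p = 0.0873), with quantile normalization (log2 difference 2.16, adjusted p = 0.108) and with the authors' processed values (log2 difference 1.45, adjusted p = 0.503, the highest over the alternatives). Edn1 read 1.21 (SE 0.23, adjusted p = 0.0151), a call lost without E11 p63-/- replicate 2 or p63+/- replicate 1 (highest adjusted p = 0.125), with the authors' processed values (adjusted p = 0.0941) and in the fit of the E11 arrays alone (adjusted p = 0.242). Of the general epithelium list 4 genes rose (11 when adjusted over the list alone; adjusted p = 0.0124 with an estimated correlation), and of the p63 pathway list 4 fell (5, with 1 higher, when adjusted over the list alone; adjusted p = 0.00569 with an estimated correlation). In the keratin list 1 of 12 genes fell, Krt15, whose call ended in 5 of 6 runs without an E11 array and under 6 of the other alternatives, with adjusted p up to 0.465 (3 fell when adjusted over the list alone), and the list's call did not hold with an estimated correlation (adjusted p = 0.184). The hemidesmosome list, with Fermt1 lower, held with it (3 fell when adjusted over the list alone; adjusted p = 0.0328). The Notch list, with Jag2 lower (-1.29; 2 genes when adjusted over the list alone), had adjusted p = 0.00701, and adjusted p = 0.129 with an estimated correlation. Lists with no gene past the threshold in limma, also when adjusted over the list alone, were higher for neuron (adjusted p = 0.00121), skeletal muscle (0.00905), macrophage (0.0124) and glia (0.0208); with an estimated correlation these became adjusted p of 0.596, 0.683, 0.570 and 0.417. At an unadjusted p under 0.05 these lists had 2, 0, 2 and 1 genes.

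At E12 Col17a1 was at least 17.3-fold lower in p63-/- prominences (adjusted p = 0.000157), at 5.30 ± 0.19 against 9.60 ± 0.95 (SD, n = 3 per genotype), and was detected on 1 of 3 p63-/- arrays. Krt14 was 8.75-fold lower (-3.13, SE 0.45, adjusted p = 0.00111), Trim29 differed by -2.43 (SE 0.27, adjusted p = 7.7e-05) and Fermt1 by -2.13 (SE 0.21, adjusted p = 2.77e-05). Wnt3a, not above background on any E12 p63-/- array, was at least 4.29-fold lower (adjusted p = 9.57e-05), and Diras2 was at least 3.41-fold lower (adjusted p = 2.77e-05). Krt8 was 4.59-fold higher, at 12.14 ± 0.56 against 9.94 ± 0.28, and Krt18 rose by 2.14 (SE 0.26, adjusted p = 0.000157), Cbln1 by 1.88 (SE 0.21, adjusted p = 7.7e-05), Cldn3 by 1.78 (SE 0.21, adjusted p = 9.57e-05) and the cystine transporter Slc7a11 by 1.64 (SE 0.23, adjusted p = 0.000756). A dimmer Slc7a11 probe read 0.36 (SE 0.19) and did not pass.

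In limma 38 genes passed at E12, 22 lower and 16 higher, with 388 at an unadjusted p under 0.05. The split was 24 lower and 11 higher with quantile normalization alone, and 21 lower and 6 higher with the authors' processed values. Without E12 p63+/- replicate 1 the count was 24, and without p63+/- replicate 2 it was 23. In a fit of the 6 E12 arrays alone, 8 genes passed and the calls of Krt14, Krt8, Jag2, Cbln1, Cldn3 and Slc7a11 were lost (adjusted p from 0.0882 to 0.426). Cryab, a small heat shock protein, read 1.51 (SE 0.28, adjusted p = 0.0193) and lost its call with the replicate number as a block (adjusted p = 0.0515), with a range over the alternatives from 0.00255 to 0.218. In the keratin list 3 of 12 genes fell (5 when adjusted over the list alone; adjusted p = 0.0267 with an estimated correlation). The calls of Krt17 and Krt5 were each lost in 4 of 6 runs without an E12 array (highest adjusted p of 0.131 and 0.211), and that of Krt14 was kept. With the authors' processed values Krt17 and Krt5 had adjusted p of 0.889 and 0.0794, and in the fit of the E12 arrays alone 0.416 and 0.740; Krt17 also lost its call with quantile normalization (adjusted p = 0.121). In the p63 pathway list 5 of 18 fell (also 5 over the list alone; adjusted p = 0.00569), and in the general epithelium list 6 of 22 rose (13 when adjusted over the list alone; adjusted p = 0.00523). The hemidesmosome list, with 3 of 15 genes lower and as many when adjusted over the list alone, had adjusted p = 0.0774 with an estimated correlation, and its Itgb4 call was lost in 5 of 6 runs without an E12 array (highest adjusted p = 0.243). The Notch list, with Jag2 lower (-1.10; 3 genes when adjusted over the list alone), passed at adjusted p = 1.1e-05, and adjusted p = 0.0164 with an estimated correlation. Skeletal muscle and hypoxia lists were higher with 0 genes past the threshold in limma, 0 and 2 at an unadjusted p under 0.05 and 0 and 1 when adjusted over the list alone (adjusted p = 1.18e-06 and 2.53e-05, and adjusted p = 0.417 and 0.0555 with an estimated correlation).

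At E13 Col17a1 was 18.9-fold lower, at 6.57 ± 0.60 against 10.81 ± 0.41 (SD, n = 3 per genotype), a log2 difference of -4.24 (SE 0.53, adjusted p = 0.000182). Krt5 and Trim29 were not above background on any E13 p63-/- array; Krt5 was at least 11.2-fold lower (adjusted p = 4.18e-05) and Trim29 at least 9.65-fold lower (adjusted p = 4.61e-07). Krt14 was 7.03-fold lower, at 10.51 ± 0.03 against 13.33 ± 0.29 (-2.81, SE 0.45, adjusted p = 0.00366). Wnt3a was at least 4.64-fold lower (adjusted p = 7.51e-05), and Hoxa5, a homeobox gene of posterior identity, at least 4.12-fold lower (adjusted p = 1.04e-07); on the authors' scale its log2 difference was -0.69. Krt8 was 5.35-fold higher (2.42, SE 0.27, adjusted p = 6.54e-05), and Krt18 rose by 2.26 (SE 0.26, adjusted p = 0.0001), Cldn3 by 1.96 (SE 0.21, adjusted p = 4.18e-05), Cbln1 by 1.77 (SE 0.21, adjusted p = 0.000125) and the sulfotransferase Chst5 by 1.38 (SE 0.20, adjusted p = 0.001).

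In limma 39 genes passed at E13, 21 lower and 18 higher, with 343 at an unadjusted p under 0.05. Without E13 p63-/- replicate 2 the count was 25, without p63-/- replicate 3 it was 24, and without p63+/- replicate 2 it was 23. Fgf17 rose by 1.71 (SE 0.28, adjusted p = 0.00501) but did not pass without p63-/- replicate 3 (adjusted p = 0.0547), with quantile normalization alone (0.121) or with the authors' processed values (0.875). Sfn read -1.56 (SE 0.33, adjusted p = 0.0461); its call was lost with the replicate block (adjusted p = 0.0771, and from 1.86e-05 to 0.2201 over the alternatives) and without any of the 6 E13 arrays in turn (highest adjusted p = 0.274). Tfap2b, a transcription factor of the odontogenic mesenchyme list, read 0.66 (SE 0.17, adjusted p = 0.161) and passed with the block (adjusted p = 0.0242, and up to 0.363 under other alternatives). In the keratin list 2 of 12 genes fell (6 when adjusted over the list alone; adjusted p = 0.00569 with an estimated correlation) and in the hemidesmosome list 3 of 15 (also 3 over the list alone; adjusted p = 0.00524). Of these the call of Itgb4 was lost in all 6 runs without an E13 array (highest adjusted p = 0.175) and with the Xist covariate (adjusted p = 0.136). In the p63 pathway list 3 of 18 fell (4, with 1 higher, over the list alone; adjusted p = 0.0182 with an estimated correlation), and in the general epithelium list 7 of 22 rose (13 when adjusted over the list alone; adjusted p = 0.00523). Notch (with Jag2 lower, -1.06), Wnt, Shh, Fgf and Bmp readouts and skeletal muscle were lower as lists, at adjusted p of 0.00404, 0.0207 and 1.95e-06, with 2, 0 and 1 genes lower when adjusted over each list alone. With an estimated correlation these became adjusted p of 0.103, 0.445 and 0.417, and the higher odontogenic mesenchyme list (1 gene when adjusted over the list alone) went from adjusted p of 0.00106 to 0.184.

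A core of genes passed at every stage. The 13 genes called at all 4 stages were Anxa8, Ctsa, Diras2, Fermt1, Jag2, Pltp, Sfn and Trim29, lower in p63-/-, and Cbln1, Cldn3, Krt8, Krt18 and Marveld3, higher. The Ctsa call rests on 1 of its 5 probes, and whether that probe reads Ctsa was not tested. Of the 52 calls of these genes at a stage, 10 were lost in some run without 1 array of the stage: those of Sfn, Diras2 and Pltp at E13, Sfn at E12, Krt8 and Krt18 at E10 and E11, and Anxa8 and Cbln1 at E10 (highest adjusted p = 0.274). Fitting the compared arrays alone ended 24 of the 52, and at least 1 other alternative ended 8 (highest adjusted p over the alternatives of 0.566). Fermt1 alone kept its call at every stage in all these fits, and Cldn3, Ctsa, Jag2 and Trim29 kept theirs in all but the fit of the compared arrays. A further 8 genes passed at 3 stages, 31 at 2 and 105 at 1. E10 and E11 shared 22 lower and 13 higher genes, and E12 and E13 shared 14 lower and 9 higher genes. With calls independent between stages, 0.161 lower and 0.0983 higher genes would be expected in common at E10 and E11. At E12 and E13 the expected values were 0.0364 and 0.0227. These stages have no array in common, but the calls rest on 1 estimate of each gene's spread, which can raise the overlap. Across all genes, which are not independent replicates, the differences of any 2 stages correlated with r between 0.179 and 0.376.

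Whether the genotype difference itself changed with stage was tested with an interaction over the 4 stages, and 2 genes passed. Hoxa5 (interaction adjusted p = 2.78e-05) was at 4.70 ± 0.05 against 7.49 ± 0.65 at E13 and was not above background on any array of the earlier stages in either genotype. Mt3 (interaction adjusted p = 0.0432) was at 6.58 ± 0.27 against 5.21 ± 0.13 at E10. It was not above background on any E12 or E13 array, so its spread also rests in part on arrays without signal. Its interaction call was lost with quantile normalization alone, the authors' processed values, no detection filter, the replicate block and without E10 p63-/- replicate 3 (adjusted p from 0.0525 to 0.369). The next smallest were Wnt3a (0.0641) and Krt5 (0.0730), so that the later appearance of the Krt5 difference was not shown to be a change with stage. In limma 427 genes had an unadjusted interaction p under 0.05. The count was 9 without E12 p63+/- replicate 3, 4 without E10 p63-/- replicate 3 or E11 p63+/- replicate 3, and 1 without any of E10 p63+/- replicates 1 to 3, E11 p63-/- replicate 3, E12 p63-/- replicates 1 to 3, E12 p63+/- replicate 2, E13 p63-/- replicates 1 and 3 or E13 p63+/- replicates 1 and 2. A count of 2 was within what random regroupings gave.

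From E10 to E13, 6771 genes passed in limma in p63+/- prominences, 3558 lower and 3213 higher at E13, with 7387 at an unadjusted p under 0.05 (n = 3 per stage). Actc1, cardiac actin of embryonic muscle, rose by 7.92 (SE 0.54, adjusted p = 3.73e-08) and Myl1, a myosin light chain, by 7.87 (SE 0.67, adjusted p = 8.39e-08). Acta1, skeletal actin, was at least 127-fold higher (adjusted p = 7.41e-08) and Ogn, an extracellular matrix proteoglycan, at least 124-fold higher (adjusted p = 5.19e-07). Fgf8, the growth factor of early oral epithelium, differed by -4.80 (SE 0.42, adjusted p = 1.03e-07), Igdcc3 by -5.69 (SE 0.56, adjusted p = 2.66e-07), the stem cell factor Sall4 by -4.76 (SE 0.42, adjusted p = 1.05e-07) and the embryonic globin Hbb-bh1 by -3.94 (SE 0.31, adjusted p = 5.43e-08), while Trim71 was at least 13.3-fold lower (adjusted p = 6.45e-07). Each stage was hybridised on its own slide, so stage and slide cannot be told apart in these values.

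All 18 skeletal muscle genes rose from E10 to E13 in p63+/- (camera adjusted p = 6.94e-14) and 12 of 13 osteogenic genes rose while 1 fell (2.72e-05), among them Col1a1 (5.01, SE 0.68, adjusted p = 7.54e-06) and Sp7, a factor osteoblasts need (3.89, SE 0.44, adjusted p = 1.2e-06). All 17 proliferation genes fell (1.82e-07), as did 8 of 10 erythroid genes (0.00111). Of the keratins and desmosomes 8 of 12 rose (0.000523), led by Krt15 (4.86, SE 0.42, adjusted p = 8.64e-08) and Krt17 (3.78, SE 0.43, adjusted p = 1.24e-06), and 19 of 22 general epithelium genes fell (5.65e-06), with a difference of -2.58 (SE 0.26, adjusted p = 4.24e-07) for Krt18. Endothelial (12 of 14, 5.34e-05), macrophage (11 of 13, 0.000523), glial (4 of 7, 0.0056), Notch (7 of 12, with 1 lower, 0.0209) and immediate early lists (9 of 15, with 2 lower, 0.0174) were higher. Adjusted over the list alone, 13 endothelial and 5 glial genes rose and the other counts were as given. None of these 11 list calls held with an estimated correlation (adjusted p from 0.251 to 0.273), and the other 10 lists did not pass.

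In p63-/- prominences 7095 genes passed between E10 and E13, 3619 lower and 3476 higher. Of the 5706 genes called in both genotypes, 5701 moved in the same direction and 5 in opposite directions, and the E13 minus E10 differences of the genotypes correlated with r = 0.92 across genes. Krt14 read 1.31 (SE 0.45, adjusted p = 0.019) in p63-/-, a call lost without E10 p63-/- replicate 2 (adjusted p = 0.0636), against 2.81 (SE 0.45, adjusted p = 4.21e-05) in p63+/-, and Krt8 -1.12 (SE 0.27, adjusted p = 0.00166) against -2.28 (SE 0.27, adjusted p = 1.85e-06). Col17a1 was at least 1.94-fold higher (adjusted p = 0.00736) at E13 in p63-/-, a call lost with the authors' processed values (adjusted p = 0.235), and rose by 4.96 (SE 0.53, adjusted p = 6.07e-07) in p63+/-. Fgf8 differed by -4.51 in p63-/- and Actc1 by 6.67. Of these genes none passed the interaction test.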

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

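The tests of yolk sac RNA, of epithelial shares and of Hoxa5 in this part were chosen after the results were seen; the regroupings of the arrays were planned.

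A test of the difference between stages singled out 2 genes whose genotype difference varied. For Hoxa5 the interaction adjusted p was 2.775e-05, with all 3 E13 p63-/- arrays below all 3 E13 p63+/- arrays. For Mt3 it was 0.04321, with all 3 E10 p63-/- arrays above all 3 E10 p63+/- arrays, and the call was lost under 5 of the settings run (adjusted p from 0.05245 to 0.3689). Both interaction p-values use a spread shared with groups in which the gene was not above background. In limma the count of 2 was reached or passed by 12 of 100 random regroupings, the real one included, with a highest other count of 8, so chance cannot be excluded for the count.

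Regrouping the arrays gave these counts for the other comparisons. Averaged over the stages, 1 of 100 regroupings, the real one, reached the 298 genes, against a highest other count of 3. A share of 1 in 100 is the smallest these regroupings can give. The other regroupings hold the genotype difference in their spread, which can lower their counts, so they do not exclude chance by themselves. The 7 gene lists on the average were reached by 30 of 100 regroupings, with a highest other count of 11, and chance cannot be excluded for the number of lists. These random regroupings did not keep same-number arrays apart, and a version that did was not run for the average, the lists or the interaction. Within a stage the 6 arrays allow 10 splits, too few for a share under 0.05. The real split, 1 of 10, gave 101 genes at E10 and 65 at E11, with highest other counts of 1 and 2. It gave 38 at E12 and 39 at E13, with highest other counts of 24 and 33. The splits with those other counts kept replicates 1 and 3 of both genotypes together and parted replicate 2, so they follow the replicate number. With the replicate number as a block 49 genes passed at E12 and 46 at E13, with 32 of the 38 and 33 of the 39 genes of the main fit among them. Between E10 and E13, also with 10 splits, the real counts of 6771 in p63+/- and 7095 in p63-/- stood against highest other counts of 0 and 136.

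The array E10 p63-/- replicate 3 carried yolk sac transcripts. Of 34 visceral yolk sac endoderm genes on the array, 29 lay over 1 log2 unit above the mean of the other 5 E10 arrays, with a median difference of 5.448, and 14 of the list were detected on all those arrays and 1 was also in another fixed list. Mandibular patterning genes differed by -0.5591 in the median, which argues against another tissue in place of the prominence. Alb moved by 0.03804, but it was not detected on any other E10 array or any later array, so its probe was not shown to report liver RNA. The 12 hepatocyte genes moved by 0.2612 in the median, 2 of them by over 1 log2 unit, and liver is not excluded. RNA of visceral yolk sac endoderm in that sample is a candidate source, with Ttr at 15.47, Apoa1 at 15.12 and Afp at 13.77. Whether a piece of membrane or its free RNA came along stays open, and no biological explanation was tested.

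On the average 14 of 22 general epithelium genes were higher in p63-/-, and 9 genes of the keratin and hemidesmosome lists were lower. A change in the share of all epithelial cells alone would move both sets the same way. The general epithelium median was 0.5519, while those 9 genes were lower, with none higher in either list in limma. The opposite directions argue against a smaller or larger share as the only change. These values also define the pattern, so a changed share together with changed expression per cell is not excluded. Of the 14 general epithelium genes called on the average, 13 were also called on the average of E11, E12 and E13. Those stages are part of the average that chose the 14, which favours this result. Over all 22 genes, not chosen by their calls, the median was 0.516 on the average of E11 to E13, against 0.552 over 4 stages. That argues against yolk sac RNA at E10 as the whole cause. Epithelium that stays simple in the absence of p63 is a candidate explanation that these tests leave open. Single prominences hold epithelium and mesenchyme together, so a change within epithelial cells and a change in which epithelial cells are present cannot be separated here.

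Hoxa5 was not detected on any E13 p63-/- array, at 4.70 ± 0.05 against 7.49 ± 0.65. With the Xist level as a covariate the difference was -2.742 (SE 0.21, adjusted p = 2.14e-06). This cannot decide on embryo sex, since the 3 E13 p63+/- arrays, which alone carry the signal, hardly differed in Xist (4.64 to 4.68). E13 p63-/- replicate 2 also had a low Xist level (4.79) and no Hoxa5 signal. That is 1 embryo, so embryo sex is not excluded. The 9 other Hox genes detected on all 6 E13 arrays differed by -0.4749 in the mean, 7 of them lower and 0 past the threshold within the family in limma (2 at an unadjusted p under 0.05, lowest adjusted p = 0.193). With the replicate number as a block Hoxa2, Hoxb2 and Hoxd3 passed within the family (adjusted p from 0.00721 to 0.0444), lower in all 3 same-number pairs. Adjusted over all genes tested, none of them passed in that fit (adjusted p = 0.368, 0.693 and 0.131). Less posterior tissue in the E13 p63-/- samples may account for the value and cannot be told apart from a genotype effect, since the other Hox genes are the only measure of it here and 2 of the 9 were not lower.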

How the results depend on the processing

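The fits without E10 p63-/- replicate 3 and with the Xist covariate were chosen after the data were seen; the other alternatives were planned. No call of a named gene changed direction under any setting run. Array weights raised the counts, to 295 genes at E10, 119 at E11, 62 at E12, 273 at E13, 600 on the average and 67 for the interaction. Fitting the compared arrays alone, with fewer arrays behind the spread, gave 26 at E10, 26 at E11 and 8 at E12. The authors' processed values gave 35 at E11. A fold change of at least 1.5 left 133 on the average, 4151 for E13 minus E10 in p63+/- and 4506 in p63-/-; testing all detected probes gave 12112 and 12818 for the latter contrasts. The interaction count was 4 with an offset of 50 and without E10 p63-/- replicate 3, 1 with no detection filter, with all detected probes and with the replicate block, and 0 in limma with the strict filter (319 at an unadjusted p under 0.05), which leaves Hoxa5 untested. The causes of the other shifts were not tested.

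At E10 and E11 same-number samples carry consecutive sample identifiers, as at E12 and E13, but deviated together less. Same-number correlations were 0.042 to 0.190 and 0.074 to 0.199, and 5 and 4 of 6 arrays correlated best with their own number. Among named genes the block ended the Krt8 call at E10 and E11 (adjusted p = 0.0574 and 0.0510). With it Krt14, Krt17, Osr2, Sox10 and Ngfr passed at E10 and Hapln1 at E11 (adjusted p from 0.0115 to 0.0350). The replicate block gave 205 genes at E10, 97 at E11 and 384 on the average, and 49 at E12 and 46 at E13, where over all genes it changed no call of a gene that the rule took at that stage, or that was called at all 4 stages, other than those of Cryab, Sfn, Diras2 and Tfap2b.

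Leaving out each array in turn gave 51 to 430 genes at E10, 28 to 93 at E11, 23 to 49 at E12, 23 to 52 at E13, 234 to 341 on the average, 1 to 9 for the interaction, 5762 to 7205 and 6202 to 7251 for E13 minus E10 in p63+/- and p63-/-, and 5 to 10 lists. Of the named genes called, 16 of 24 kept the call in all these runs at E10, 9 of 22 at E11, 13 of 22 at E12, 13 of 20 at E13 and 42 of 45 on the average, with 0 changes of sign. With the further genes and stages named in the text, at least 1 other alternative ended 19 of 29 calls at E10, 17 of 26 at E11, 18 of 26 at E12, 10 of 25 at E13 and 6 of 52 on the average; without the fit of the compared arrays alone these were 8, 8, 8, 7 and 6. Signal over background limits dim genes: 43.4% of probes were detected on the array with the fewest.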

Other observations

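The families, the sex-linked genes, the neighbours of Trp63 and the neighbouring gene pairs in this part were chosen after values had been seen; the test of developmental position was written beforehand, and its version with paired arrays was added later.

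Of 20 measured keratin genes 4 were higher on the average (Krt7, Krt8, Krt18 and Krt19) and 4 lower (Krt5, Krt14, Krt15 and Krt17), and of 14 claudin genes 5 were higher (Cldn3, Cldn4, Cldn6, Cldn10 and Cldn23) and 0 lower in limma. The same counts were found with quantile normalization alone, with an offset of 50 and with the authors' processed values.

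The Xist level, high in female embryos, was unevenly spread over the groups. All 3 E12 p63+/- arrays read between 11.49 and 11.78 and all 3 E13 p63+/- arrays between 4.64 and 4.68, while each p63-/- group held both high and low arrays. The Y-linked gene Eif2s3y read at least 10.05 on every array with low Xist. Among arrays with high Xist it read 6.99 on E10 p63-/- replicate 2, 6.84 on E11 p63-/- replicate 3 and 7.57 on E11 p63+/- replicate 2. On the others with high Xist it read at most 5.98. The source of this signal was not tested. With Xist as a covariate 113 genes passed at E10, 60 at E11, 31 at E12, 31 at E13 and 299 on the average. On E10 p63-/- replicate 2 the visceral yolk sac endoderm genes differed from the E10 p63+/- mean by 0.271 in the median; Afp read 8.33 against at most 6.00 and Ttr 10.17 against at most 7.98.

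A hypothesis was that p63-/- prominences lag or lead in development. Each array was placed along the change between 2 other stages, taken over both genotypes, and p63-/- arrays lay at -0.0554 days relative to p63+/- arrays of the same stage (SE 0.11, mean over 4 stages). A permutation of genotypes within stages gave an exact two-sided p of 0.587 over 160000 relabellings, and the stage differences ran from -0.0642 to -0.0381 days. With same-number arrays taken as pairs at E12 and E13, the SE was 0.0675 and the exact p 0.378 over 25600 relabellings. The mean and 2 SE to either side then reach from -0.19 to 0.0796 days, so no shift was shown and a lag of 0.1 days is not excluded.

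A further hypothesis was that sequence around the targeted allele, carried along from the strain in which it was made, could account for the called genes. Among the 100 measured genes nearest Trp63, 50 on either side, 1 other called gene was found, Etv5, so 0.3367% of the other called genes lay there. That is 1 of 100 genes called, against 2.35% of the genes elsewhere. This argues against it as the source of the called genes as a set.

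Genes called on the average lay next to each other more often than random genes did. There were 21 neighbouring pairs in the order of measured genes, against a median of 7 and a highest of 18 in 10000 random draws of as many genes (one-sided permutation p of 1e-04, the smallest these draws can give). In 16 pairs both genes moved the same way, among them Krt8 with Krt18, Krt14 with Krt17 and Cldn3 with Cldn4. Families that arose by duplication and are used in the same cells may account for part of the 21. Ctsa and Pltp, which are not of 1 family, are also neighbours and were both lower at all 4 stages, with the Ctsa signal resting on 1 of its 5 probes. Whether that probe reads Ctsa was not tested, so the 2 need not be separate signals.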
